A study of Drosophila melanogaster with 4 samples.

How the data were processed

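Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on embryos of the w[1118] strain of Drosophila melanogaster, a white-eyed laboratory stock listed as wild type, per the labels. The series holds 4 samples: an Insensitive (Insv) immunoprecipitation and an IgG control at each of 2 collection windows, 2.5-6 h and 6.5-12 h. Each group has 1 sample, so no replicate error exists for any value. Peak lists of the 2 Insv samples were used; data of the IgG samples were not analysed here. Per the labels' protocols, nuclei were sonicated, complexes were isolated with antibody, and adapter-ligated, PCR-amplified and gel-selected fragments were sequenced on an Illumina Genome Analyzer. Those protocols mention no molecular identifiers.

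Bowtie, a short-read aligner, and the genome build dm3 are named in the submitters' processing notes. The peak caller, its threshold and the use of the IgG reads are not given in the sources used here. Each deposited file is a list of called positions of a fixed width of 2 bp, with a name that holds a running number and a rank, and a score. The score is the authors' own value, deposited without a named scale, and was used to order, describe or filter positions within its own list. The scales of the lists are not known to be shared, so early and late scores of paired positions are set side by side only as a description. The number of reads behind each list is not stated, so the depth is unknown and no interval on a score can be given. A rank number was often carried by several positions on different chromosomes (2347 distinct numbers for 5364 early positions), and ranks were not used.

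Coordinates were converted to 1-based dm3 coordinates and no other build was used. Neither a dm3 sequence nor a dm3 gene annotation was used here, and the gene table at hand belongs to Release 6 of the genome, so positions are named by coordinate and no gene, transcription start site or sequence motif was assigned. Of the analyses fixed before the data were examined, 6 could therefore not be run: the promoter-proximal share, the Insv binding site, the other binding sites, the site by peak class, the gene lists, and the genes with a promoter peak in 1 stage. The rule for named items fixed beforehand for that case was the 10 highest-scoring positions of each list. Other positions and regions named were chosen after their values were seen.

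The planned criterion for a shared position was an overlap of at least 1 bp. Because the deposited positions are 2 bp wide, that criterion asks for the same base or its neighbour, and a distance of up to 200 bp between positions, also fixed beforehand, was used as the main criterion instead; the overlap values are given in the closing part. A position had a partner when the nearest position of the other list lay within 200 bp. Mutual pairs were positions that were each other's nearest and lay within 200 bp. The number of partners was compared with 1000 circular shifts of the late list along each chromosome, between the first and last position of either list, which keep the spacing of positions. Scores of positions with and without a partner were compared within each list by a two-sided permutation test of the difference in medians (100000 resamples; the smallest p it can give is 1e-05). Each list was divided by its own score into deciles, of which decile 1 is the lowest and decile 10 the highest. Regions were made by chaining positions up to 1000 bp apart, and wider groups by chaining up to 5000 bp; positions of the other list were counted in such an interval when they lay in it or within 200 bp of its ends. Spacings were compared with 200 random placements of the same number of positions per chromosome. Intervals on shares are 95% exact binomial (Clopper-Pearson) intervals, and where a count was 0 the limit given is 3 counts of the total; both cover counting error only and treat positions as independent, although many lie close together. All p-values are across positions of single libraries and compare these lists, not replicated conditions.

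Alternatives tried were other distances, an overlap criterion, the top 50% of each list by score, lists of equal length, the main arms alone (2L, 2R, 3L, 3R, 4 and X), and regions in place of positions. Width in place of score was not tried because every position has the same width. The code was tested on simulated lists of the real sizes: with 60% of 2390 late positions copied from the early list with a jitter of 10 bp (SD), 60.6% were found shared and the recovered SD was 10.1 bp, and shifts of that list gave 1.81%. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.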

Results

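Insv is a nuclear BEN-domain protein of Drosophila, known as a DNA-binding transcriptional repressor that acts in the nervous system and with the Notch pathway. Its genome-wide binding was recorded in w[1118] embryos of 2 age windows, 2.5-6 h (early) and 6.5-12 h (late), with 1 Insv library per window. The early list held 5364 called positions and the late list 2390, a ratio of 2.24. Scores ran from 2.54 to 307 in the early list, with a median of 11.3 and quartiles of 7.47 and 20.7. Late scores ran from 2.53 to 200, with a median of 13.6 and quartiles of 8.71 and 28.8. The 2 lists are not known to share a score scale. There were no replicates, and the depth of the libraries is unknown.

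Where in the genome the positions lay was examined first. All 5 large arms carried Insv positions at both ages, over spans of 20.5 Mb (2R) to 27.9 Mb (3R). In the early list, X had the highest density, 49.1 positions per Mb (1089 positions), followed by 2R with 47.5 (973), 3R with 46.3 (1290) and 3L with 45.7 (1078). Arm 2L was lowest of the large arms with 40.8 per Mb (897), and the small chromosome 4 had 21.4 per Mb, from 25 positions. In the late list X was again highest, with 23.7 per Mb (527 positions), and the other large arms lay between 18.0 on 2L and 20.7 on 3R. Chromosome 4 had 12 late positions, or 10.3 per Mb. Off these arms, the early list had 12 positions and the late list 2, on heterochromatic or unplaced sequence. Densities refer to the span between the first and last called position of an arm. Regions of chained positions gave another order in the early list: 2R had 32.2 regions per Mb, 3R 30.3 and X 29.1.

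**Figure D1:**
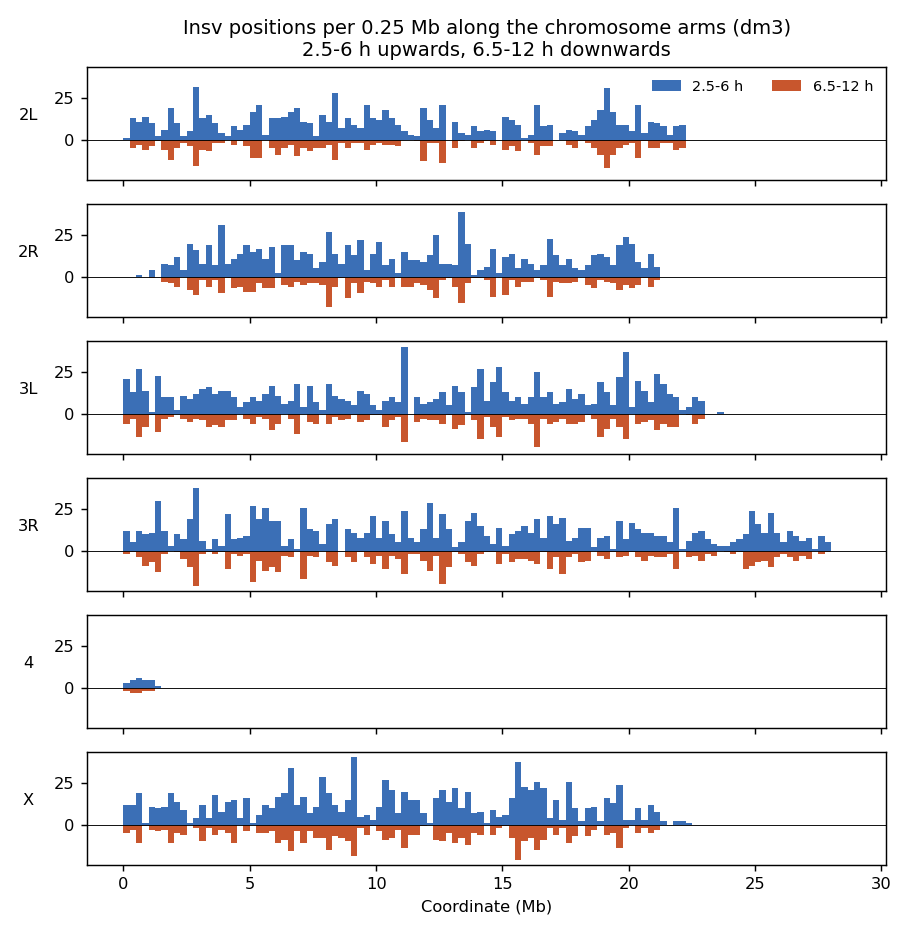
Number of called Insv positions per 0.25 Mb (vertical axis) along chromosome arms 2L, 2R, 3L, 3R, 4 and X (horizontal axis, Mb, dm3), with the 2.5-6 h list drawn upwards and the 6.5-12 h list downwards. X, the arm with the highest density in both lists, has 1089 early and 527 late positions.

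Called Insv positions were grouped along the chromosomes relative to uniform random placement. Whether close positions are separate binding sites was not tested. In the early list, 1935 of 5355 spacings between neighbours (36.1%) were 1000 bp or less, against a mean of 4.51% and a maximum of 5.17% in 200 random placements. In the late list 820 of 2382 spacings (34.4%) were this short, against a mean of 2.11% and a maximum of 3.11%. Short spacings had a median of 325 bp early and 319 bp late, and no neighbours were closer than 90 bp early or 86 bp late. Chaining gave 3429 early regions, of which 965 held 2 or more positions, and these held 54.1% of all early positions. The late list formed 1570 regions, 481 of them with 2 or more positions, which held 54.4% of late positions.

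The regions richest in positions, chosen after their values were seen, included 3 on X among the 8 richest of the early list. Positions of the other list were counted up to 200 bp beyond the ends of a region. The early region at X 15995617 to 15999941 held 11 positions with a top score of 143, and 6 late positions were counted with it. At X 3999951 to 4003970 there were 10 early and 5 late positions. The region at X 9176032 to 9178494 held 9 early and 8 late positions. On 2L, the region at 19131955 to 19134925 held 9 early and 6 late positions, and that at 2855728 to 2857705 held 8 early and 7 late. The richest late region lay at 2L 11806178 to 11809420, with 10 late positions and 8 early ones.

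Wider groups, chained at 5000 bp, showed different proportions of early and late positions, where the whole lists held 2.24 early positions per late one. The groups named were the richest of the early or of the late list, which favours the count of the list used. The largest lay at X 6568433 to 6595318, a stretch of 26886 bp with 20 early and 8 late positions and top scores of 143 and 75.1 in the respective lists. The next, at 3R 21843167 to 21868577, spanned 25411 bp with 17 early and 4 late positions. Its top scores were lower, 41.5 early and 32.4 late. At X 8785772 to 8802734 there were 15 early and 9 late positions, and at 3R 5694380 to 5707239 there were 14 and 6. The group at 3L 16401019 to 16412809 had 11 late positions beside 13 early ones. At 2R 12466860 to 12476718, 9 late positions lay beside 13 early ones. Differences in proportion between these groups were not tested.

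**Figure D2:**
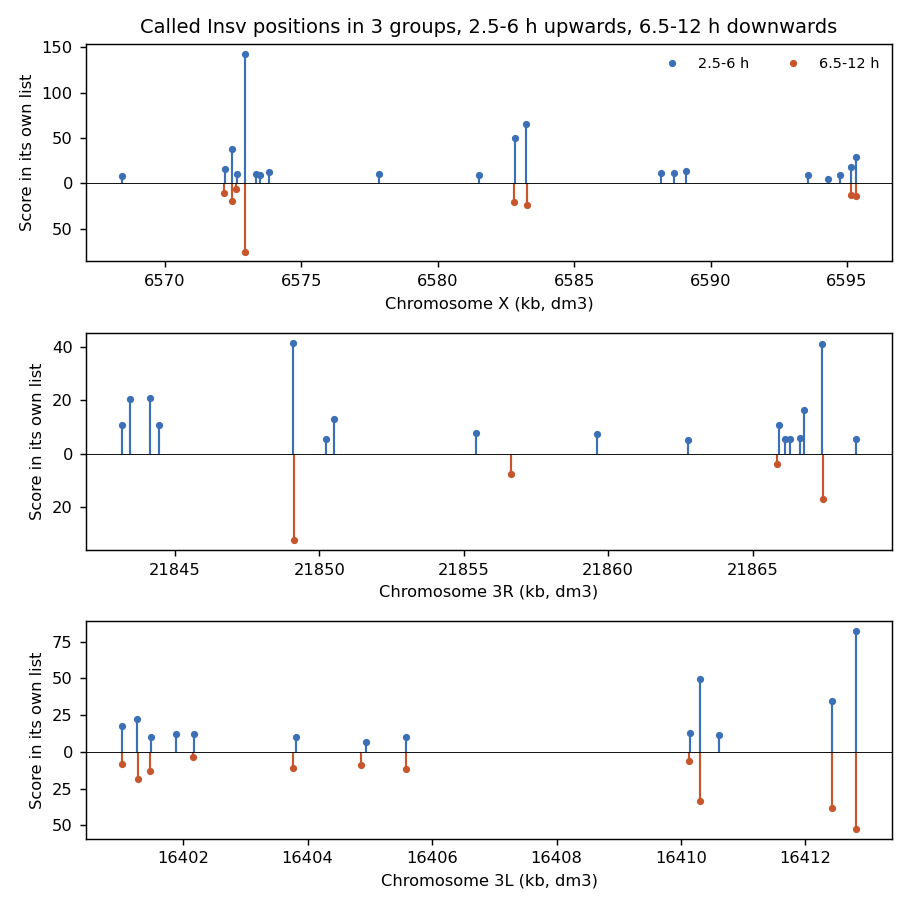
Called Insv positions in 3 groups, on X, 3R and 3L (horizontal axes, kb, dm3), with the score in its own list as the height of each stem, 2.5-6 h upwards and 6.5-12 h downwards. The groups hold 20 early and 8 late, 17 early and 4 late, and 13 early and 11 late positions; the score scales of the lists are not comparable.

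The design asks how Insv binding in the younger embryos compares with that in the older ones. Nearly every late position had an early counterpart, while the larger part of the early positions had no late one within 200 bp; within 500 bp, 52.0% of early positions had one, and within 1000 bp 56.8%. Of the 2390 late positions, 2260 (94.6%, 95% interval 93.6 to 95.4) lay within 200 bp of an early position. Of the 5364 early positions, 2325 (43.3%, 42.0 to 44.7) lay within 200 bp of a late one. Circular shifts gave a mean of 1.72% and a maximum of 2.89% for the late list, and 0.772% and 1.34% for the early list, and none of 1000 shifts reached the observed counts. Both shares depend on the lengths of the lists. With the early list cut to its 2390 highest-scoring positions, the early share rose to 69.96% and the late share fell to 70.2%.

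Paired positions lay close to each other. Mutual pairs lay within 200 bp by definition. Among 2233 such pairs the median distance was 8 bp with an upper quartile of 15 bp, and 1858 pairs (83.2%) were within 20 bp. The median signed distance, late minus early, was 1 bp. Pairs whose early score was in decile 10 were 6 bp apart at the median (533 pairs), and pairs with an early score below the median were 10 bp apart (508 pairs). Across pairs, the early and late scores had a Spearman rho of 0.73 and a Pearson r of 0.75 on the log2 scale. These are correlations across positions of 2 libraries, and positions are not independent replicates.

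**Figure D3:**
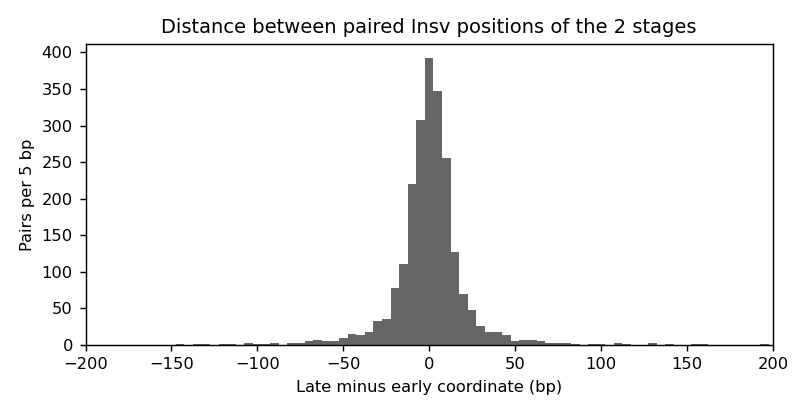
Histogram of the distance between mutual pairs, as the late minus the early coordinate in bp (horizontal axis), with the number of pairs per 5 bp on the vertical axis. The 2233 pairs, all within 200 bp by definition, form a single narrow peak centred near 0, with a median absolute distance of 8 bp.

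Whether an early position had a late partner followed its score. In decile 1 of the early list, the lowest-scoring, 15.9% of positions had a late partner (95% interval 12.9 to 19.2), and in decile 6 it was 34.0% (29.95 to 38.1). The share was 63.3% (59.1 to 67.4) in decile 8 and 88.4% (85.4 to 91.0) in decile 9. In decile 10, the highest-scoring, 536 of 537 positions (99.8%, 99.0 to 99.995) had one. Early positions with a partner had a median score of 21.8 (quartiles 11.5 and 45.7), against 8.99 (6.46 and 12.2) for the 3039 without, a difference of 12.8 (two-sided permutation test, p = 1e-05, the smallest it can give). The difference was 7.43 when a partner within 1000 bp counted.

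In the late list the share with an early partner was high throughout. It was 83.3% (77.9 to 87.8) in decile 1, and none of the 478 positions in deciles 9 and 10 lacked a partner, which allows a share of up to 0.628%. The 2260 late positions with a partner had a median score of 14.2 and the 130 without had 8.64, a difference of 5.59 (two-sided permutation test, p = 0.00078). With the highest score of each region in place of single positions, the difference was 5.96 (same permutation test, p = 0.020).

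**Figure D4:**
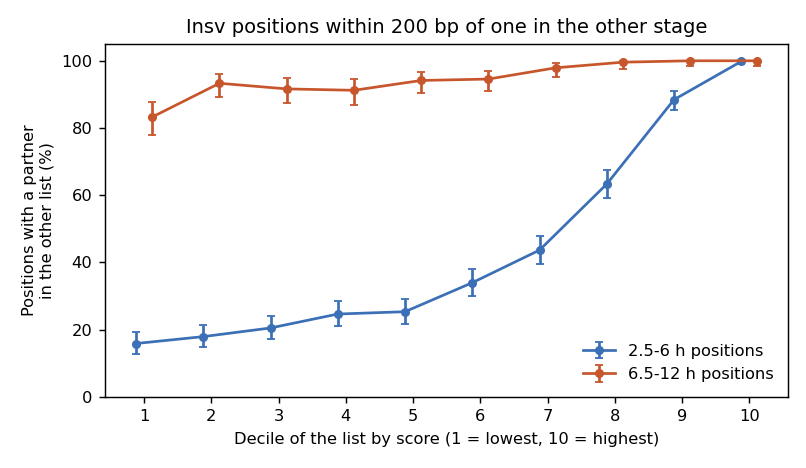
Percentage of positions with a partner within 200 bp in the other list (vertical axis) by decile of the list's own score, lowest to highest (horizontal axis); bars are 95% exact binomial intervals, which cover counting error only. Early positions rise from 15.9% to 99.8%, and late positions lie between 83.3% and 100%.

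Regions with several early positions had a late partner more often than lone positions. Of 2464 early regions with a single position, 30.4% (28.6 to 32.3) had a late position within 200 bp, against 61.1% (56.8 to 65.3) of 530 regions with 2 positions and 90.6% (87.4 to 93.2) of 435 regions with 3 or more. A region counted when any of its positions had a partner, so regions with more positions had more chances of one. The top scores of these classes differed too, with medians of 9.36, 18.2 and 53.1. In the late list, 93.4% of the 1089 single-position regions and 200 of 201 regions with 3 or more positions had an early partner.

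The 10 highest-scoring positions of each list all had a partner in the other list, at most 9 bp away for the early and 12 bp away for the late list. Of the 10 early positions, 6 were on X and none on 3R or 3L. The highest score, 307, belonged to X 11049128 to 11049129, whose late partner 9 bp away scored 66.8 and was number 191 in the late list. A second position 1 kb further along X, at 11050238 to 11050239, scored 177 early, and its partner was number 162 late with 71.2. The position at 2L 5799705 to 5799706 scored 251 early, with a late partner of 94.1. On X, the positions at 7056778 and 8801070 (first base) scored 202 and 197 early and were numbers 22 and 12 in the late list. The others were at 2R 6670397, 2R 10028542, 2R 11735639, X 1816985 and X 16217245, with early scores between 176 and 197.

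The late list was headed by 3 positions on 3R. The position at 3R 12724295 to 12724296 scored 200, that at 3R 24973997 to 24973998 scored 198.4 and that at 3R 24864858 to 24864859 scored 198.1. Their early partners were 7, 4 and 6 bp away and were numbers 47, 48 and 87 in the early list. The position at 2R 11735640 scored 195 late and 179 early, and that at 2R 10028540 scored 183 late and 186 early; these 2 pairs were the ones in the top 10 of both lists. Further late positions were at 3R 26292977, X 301698, 2L 13445717, X 6737988 and 2R 13356722, with late scores between 162 and 182. Orders in lists of different length do not measure a change in binding.

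Positions far from any position of the other list had low scores. At more than 1000 bp from the nearest late position, there were 2316 early positions (43.2%) with a median score of 8.67. At more than 1000 bp from the nearest early position, there were 76 late positions (3.18%) with a median score of 9.11. Among the early ones, 1 was in decile 10: 3R 9112059 to 9112060, with a score of 63.2 and the nearest late position 95479 bp away. The next, at 3R 7836521 to 7836522, scored 44.8, with the nearest late position 122673 bp away. Among the late ones, the highest score was 28.6, at 3R 7112857 to 7112858, with the nearest early position 15955 bp away, and 604 late positions scored higher. These positions were chosen after their values were seen.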

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

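The tests in this part that were added after the data were seen are those with partners within 20, 50, 500 or 1000 bp, those with regions in place of positions, and the score test on the main arms alone. In all of the alternatives run with a test, more positions were shared than in any of 100 shifts, and positions with a partner scored higher than those without, past p = 0.05 in both lists (two-sided permutation test). The late score difference ranged from 4.80 to 5.96, with p up to 0.020, and the early one from 7.43 to 16.6. The shared percentage itself depends on the criterion. With the planned overlap of at least 1 bp, which for positions 2 bp wide is the same as 50% of both, 10.1% of late and 4.51% of early positions were shared (242 each). With partners within 20 bp the values were 77.7% and 34.6%, and within 1000 bp 96.8% and 56.8%. With lists of equal length they were 70.2% and 69.96%, and with the top 50% of each list 91.8% and 42.2%. The top 50% held 2682 early and 1195 late positions by construction, and the main arms alone held 5352 and 2388. No paired analysis was possible because each group has 1 sample, and no replicate could be left out for the same reason. Alternative settings for promoters, binding sites and gene lists were not run because no sequence or annotation of dm3 was used here, and width in place of score was not run because all positions have the same width. Read depth is unknown, so it cannot be said how many of the early positions without a partner lay just under the late calling threshold.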

Other observations

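Except for the tests of recurrence within deciles of score over all deciles, the tests in this part were chosen after the results were seen. Insv positions on X had higher median scores than those on the autosomes at both ages. The early median was 13.2 on X (1089 positions) and 10.8 on the autosomes (4263), and the late medians were 16.4 (527) and 12.9 (1861). The differences of 2.35 and 3.49 had p = 1e-05 and p = 3e-05 in two-sided permutation tests over positions, and the top scores of regions also differed, by 2.47 and 4.62. X had the highest median of the 5 large arms in both lists, while the other early medians ran from 10.4 on 2R to 11.2 on 2L. The share of scores above 10 was 72.7% on X and 55.9% on the autosomes early, and 78.7% and 66.1% late. Among scores above 10, a subset set by the score itself, the X median differed by -0.21 early (permutation p = 0.70) and 0.98 late (permutation p = 0.46). With 1 X against 4 autosomal arms, the arms themselves are too few to test. Of the early X positions, 48.1% had a late partner, against 42.2% on the autosomes.

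Higher scores on X were weighed against 2 technical explanations. Part of the scores above 10 were whole multiples of a fixed step, within 0.75 units of the last printed digit (0.0340 early, 20.8% of such scores; 0.0298 late, 45.0%), where the best step for the same scores jittered by up to 1% takes 1.51% and 1.59%, so that a ratio to control reads held at a floor is a candidate source of these scores. Such scores were more frequent on X (29.2% against 18.0% of scores above 10 early, 58.3% against 40.5% late). With them left out, the median of the remaining scores was higher on X by 1.80 early (p = 1e-05) and 1.52 late (p = 0.027, two-sided permutation tests). Of these remaining scores, 65.4% on X and 51.0% on the autosomes were above 10 early (Fisher's exact test, p = 1.6e-14). The late shares were 60.7% and 53.8% (Fisher's exact test, p = 0.036). An X excess thus remained without the scores found on the step. The remaining scores hold nearly all scores of 10 or less, so these values cannot decide whether a floored control was the whole cause. Above 10 alone, the median of the remaining scores differed by -1.02 (permutation p = 0.15) and 1.94 (permutation p = 0.37). Only 2 of 2175 early and 0 of 742 late scores of 10 or less were found on the step. The step was fitted to scores between 10 and 30, and the tolerance was finer below 10, so low scores on it could be missed. The split therefore does not sort the low scores. A control floor among the low scores is not excluded. A fixed minimum of reads combined with a ratio score and fewer X copies in males could also raise X scores; the 10th percentile of X scores was 1.23 times the autosomal one early and 1.32 times late, but the 90th percentile was also higher, by 1.26 and 1.19 times, and without the caller's settings or the sex of the embryos this stays open, as does a difference in binding on X.

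The shorter late list was weighed against 3 explanations. For replacement of the strongest sites between the ages, 1 of 537 early positions (0.186%) and 0 of 239 late positions in the highest-scoring decile lacked a partner. This allows up to 1.03% and 1.26%, and argues only against loss of the strongest called positions from the other list. A partner of any score counted, so a change in strength is not covered. Both shares were known before this explanation was considered. A late list in which fewer weak positions passed the calling threshold, and weaker binding at every site in the older embryos, could both give the gap of 84.0 percentage points between the highest- and lowest-scoring decile of early positions with a late partner, and cannot be told apart by it; the gap was known before either was considered. Late scores at paired positions were 0.702 times the early ones at the median and higher than the early ones in 28.9% of pairs, but the lists' score steps differ, so a shared scale is not established. A difference in sequencing depth is open for the same reason.

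Recurrence of early positions was tested for a dependence on chromosome or neighbours beyond the score, with both predictions written before the results. Within deciles of the early score, the share of X positions with a late partner differed from the autosomal one by -1.06 percentage points (SD of permutations 1.39, two-sided permutation p = 0.45), so the unstratified difference of 5.92 points is not kept at equal score. Positions with another early position within 1000 bp had a late partner within 50 bp in 49.0% of cases and lone positions in 29.5%. Within deciles the difference was 1.86 points (SD of permutations 1.18, p = 0.12), with an upper bound of 4.16, so that most of the unstratified 19.5 points goes with the score, and a smaller dependence on neighbours is not excluded. The deciles did not all go one way: positions with a neighbour recurred less often in 6 of 10 deciles, and the sign of the pooled value rests on decile 8 (65.9% against 45.3%), without which it was -0.86 points (SD of permutations 1.16, permutation p = 0.46).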
